A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

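RNA from the haploid yeast strain BY4742 was sequenced as paired-end reads in 12 libraries, 3 biological replicates in each of 4 media that combined 2% or 0.5% glucose with 7 or 1 mM potassium chloride. Per the labels, reads were aligned to genome build R64 with STAR 2.7.1a and quantified with RSEM 1.3.3. The deposited values were expected counts per gene, deposited as whole numbers (0 values were not whole). The table held 46904 rows, of which 7127 carried SGD identifiers and 39777 carried WBGene identifiers. No supplied table named the WBGene rows, and they took no part in the comparisons except as an alternative scaling.

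Of the SGD rows, 6444 (90.4%) matched the supplied R64 annotation, from which gene names and coordinates were taken, and 683 did not. The libraries held 5634205 to 7036345 counts at SGD rows, and a floor of 3 counts was taken where a group had none. Rows with enough counts were kept with the default filter of edgeR, which left 6127 genes. Libraries were scaled with TMM over SGD rows. In edgeR 4.0.16, a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, with robust estimation and 8 residual degrees of freedom. The common biological coefficient of variation was 0.2405.

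The comparisons were the effect of potassium at each glucose level, the effect of glucose at each potassium level, both restrictions against neither, the single restrictions against each other, and the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. The 31 gene lists, the comparisons, the thresholds and most alternatives were chosen before the data were examined. The lists covered transport, nutrient signalling, metabolism, translation, respiration, stress, cell division, markers of other cell types and signs of RNA quality. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Per comparison, the genes to be named were the 6 highest and 6 lowest called genes with a mean of at least 10 CPM and groups that did not overlap, without this last condition for the interaction. To these were added the 3 members with the smallest p of each of the 6 lists with the smallest camera p, up to 2 members that moved against each list, and TRK1, TRK2, PMA1, ENA1, TOK1 and genes that mark the strain. A gene named in 1 comparison could be given in any other. FIT2, outside this rule, was chosen after its values were seen.

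The resemblance of the single restrictions was measured across genes with Pearson and Spearman correlations and covariance. It was compared with 100 simulated draws with no effect but the same shared controls, and with the main effects. The covariance that the spread of replicates alone would give was estimated from log2 CPM within groups. Alternatives were DESeq2 1.42.0 size factors and Wald test, upper-quartile scaling, library totals, no count filter, a stricter filter, limma voom, a fold threshold of 1.5, fits to the compared groups alone, a replicate block, and leaving out each library. Alternatives chosen after seeing the data were scaling by WBGene rows, voom with quality weights, protein-coding rows alone, list counts without the library that stood apart, an estimated correlation without each library, a replicate block for WBGene rows, and the covariance from the spread of replicates.

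The procedure was tested on simulated data with 50 changed genes per fold. At 2-fold it recovered 46% to 68% of them in the pairwise comparisons and 10% in the interaction. At 4-fold it recovered 92% to 98% and 82%. False calls made up at most 5.56% of calls. A simulated shift of 0.8 on the log2 scale in 1 list was called, and 0 of 30 other lists were called by camera. Genes were drawn independently, with the same spread in every group. The simulation therefore cannot show how the tests behave with correlated genes or unequal spread. The work used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.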

Results

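RNA sequencing libraries were made from the haploid laboratory yeast strain BY4742 grown in 4 media, which combined 2% or 0.5% glucose with 7 or 1 mM potassium (K). Each of the 4 groups held 3 biological replicates, for 12 libraries. The libraries held 5634205 to 7036345 counts at yeast genes, and rows with WBGene identifiers took another 34.0% to 41.6% of all counts. Of the yeast rows, 6127 genes were tested, and values are given in CPM of yeast counts after TMM scaling. Ranges given with CPM are the standard deviation (SD) of n = 3 libraries, and errors of log2 fold changes are standard errors (SE) from edgeR. P-values measure the spread among the labelled biological replicates. Growth stage at harvest was not stated.

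The first principal component carried 38.0% of the variance and the second 31.4%. In the group with 0.5% glucose and 7 mM K, replicate 2 stood apart from its partners. Its log2 CPM values correlated with those of replicates 1 and 3 at r = 0.882 and 0.891 across genes, against 0.987 between replicates 1 and 3. It held 741 genes more than 2-fold outside the range of the other 11 libraries, and the next highest library, 0.5% glucose 1 mM K replicate 3, held 64. Its genes for cytosolic ribosomal proteins lay a median of -1.79 on the log2 scale from the mean of its partners, and those for fatty acid oxidation lay 1.68 above it. Many results that rest on this library are given with their values without it. The share of yeast counts at ribosomal RNA genes was 0.910% ± 0.112 in the 2% glucose 7 mM K group, 1.63% ± 0.563 in the 2% glucose 1 mM K group, 1.31% ± 0.123 in the 0.5% glucose 7 mM K group and 2.46% ± 0.167 in the 0.5% glucose 1 mM K group (SD, n = 3).

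**Figure D1:**
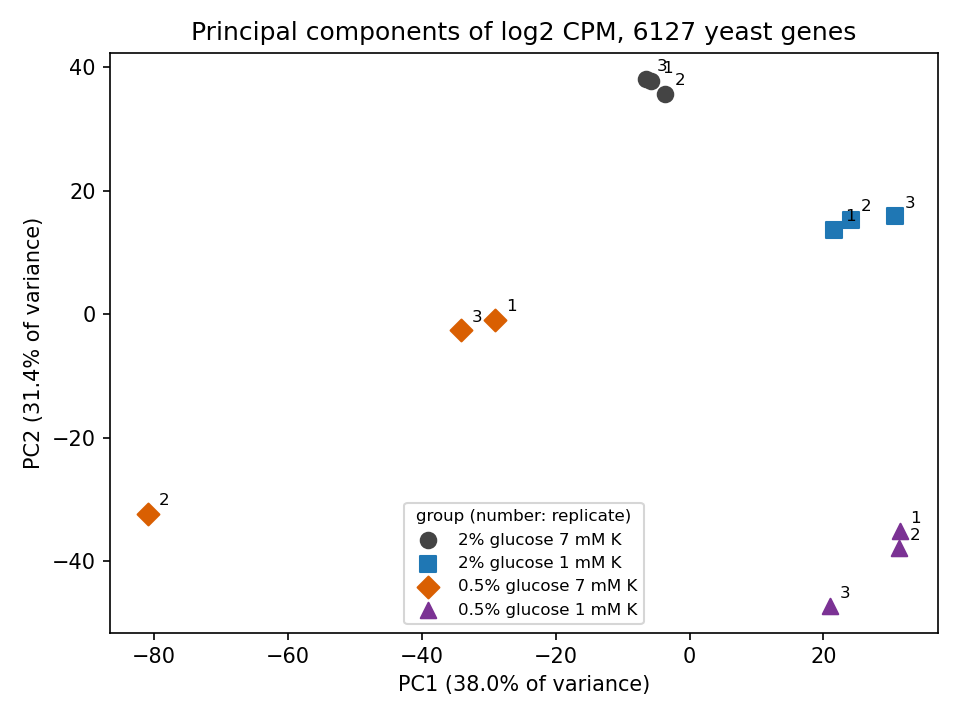
Principal components of the log2 CPM of 6127 yeast genes, with 1 point per library, labelled by replicate; the axes give 38.0% and 31.4% of the variance. Replicate 2 of the group with 0.5% glucose and 7 mM K lies far from replicates 1 and 3, and 741 of its genes were more than 2-fold outside the range of the other 11 libraries.

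The direction of many small changes depended on how libraries were scaled. Scaling by the WBGene counts instead of TMM moved the median log2 fold change of all genes to 0.26 for potassium restriction at 2% glucose, 0.24 for glucose restriction at 7 mM K, -0.15 for both restrictions, -0.40 for potassium restriction at 0.5% glucose, -0.46 for glucose restriction at 1 mM K and -0.66 for the interaction. The medians furthest from 0 were -0.26 with upper-quartile scaling and -0.34 with library totals alone, both in the interaction. Changes are therefore reported relative to the TMM scale, on which the medians lay between -0.02 and 0.03. It is not known whether the WBGene counts are a constant reference. Of 8796 such rows, 2536 were themselves called by edgeR for glucose restriction at 7 mM K.

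Potassium restriction at 2% glucose, 1 mM against 7 mM K, addressed what lower potassium changed while glucose stayed high. Camera called 12 of 31 lists, and 1, mitosis, with an estimated correlation, a call lost without any 1 of 9 of the 12 libraries. PHO89, a sodium and phosphate cotransporter gene (chromosome II, 796798 to 798522, genome build R64), rose from 12.8 ± 2.60 to 1284 ± 160 CPM, a log2 fold change of 6.64 ± 0.78 (edgeR adjusted p = 0.000106). PHO5, a repressible acid phosphatase gene (chromosome II, 429548 to 430951), rose from 30.2 ± 2.81 to 1251 ± 155 CPM, by 5.37 ± 0.27 (edgeR adjusted p = 3.12e-07). SSA4, a stress-inducible chaperone gene (chromosome V, 364589 to 366517), fell from 5039 ± 493 to 264 ± 19.5 CPM, with a log2 fold change of -4.26 ± 0.39 (edgeR adjusted p = 1.98e-05).

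Further large rises at 2% glucose were in the cyclin gene PCL1 (4.76), the phosphate regulator gene SPL2 (4.32), the glycerophosphoinositol transporter gene GIT1 (4.31) and the mating-type endonuclease gene HO (4.13). Large falls were in TDA6, a gene of unknown function (-4.37), the noncoding RNA gene IRT1 (-3.78), the polyamine exporter gene TPO2 (-3.76) and the membrane chaperone gene HSP30 (-3.34). In the mitosis and cytokinesis list, 23 of 32 genes rose, 2 fell and 7 did not pass (24 and 3 adjusted over the list alone; camera adjusted p = 1.33e-09, and adjusted p = 0.0234 with an estimated correlation). The latter was 0.255 without 0.5% glucose 7 mM K replicate 2, and 0.129 to 0.196 without 8 other libraries taken singly. Its cyclin genes CLB1 and CLB2 rose by 4.05 ± 0.26 and 3.86 ± 0.38. In the S phase and histone list, 22 of 45 genes rose and 1 fell (25 and 1 adjusted over the list alone; camera adjusted p = 2.77e-08, but adjusted p = 0.502 with an estimated correlation). Among them, the ribonucleotide reductase gene RNR1 rose by 3.73 ± 0.34 and the G1 cyclin gene CLN1 by 3.42 ± 0.21. The phosphate response list had 13 of 19 genes up and 1 down (14 and 1 adjusted over the list alone; camera adjusted p = 7.1e-06, adjusted p = 0.104 with an estimated correlation), and the ergosterol synthesis list had 12 of 24 up and 1 down (13 and 1 adjusted over the list alone; camera adjusted p = 0.000234, adjusted p = 0.246 with an estimated correlation).

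Heat shock chaperone genes fell at 2% glucose in 18 of 31 cases and rose in 1 (21 and 1 adjusted over the list alone; camera adjusted p = 1.09e-06, adjusted p = 0.567 with an estimated correlation). The chaperone gene SSE2 fell, with -2.67 ± 0.29, as did HSP78, with -1.97 ± 0.30. Autophagy genes fell in 16 of 37 cases with none up (18 and 0 adjusted over the list alone; camera adjusted p = 5.31e-06, adjusted p = 0.567 with an estimated correlation). The kinase gene ATG1 fell, with -2.10 ± 0.25. Amino acid biosynthesis genes fell in 22 of 56 cases and rose in 3 (24 and 3 adjusted over the list alone; camera adjusted p = 0.000246, adjusted p = 0.885 with an estimated correlation), and 36 fell without 0.5% glucose 7 mM K replicate 2. General stress genes fell in 16 of 48 cases with none up (17 down and 1 up adjusted over the list alone; camera adjusted p = 0.000393, adjusted p = 0.885 with an estimated correlation), and nutrient signalling and longevity genes fell in 16 of 38 and rose in 3 (18 and 3 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.556 with an estimated correlation).

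Among cytosolic ribosomal protein genes at 2% glucose, 15 of 135 rose and none fell (8 and 0 adjusted over the list alone), with a median log2 fold change of 0.59 (camera adjusted p = 1.09e-06, adjusted p = 0.885 with an estimated correlation). RPS22B rose by 2.58 ± 0.15, and RPL18B by 1.32 ± 0.23. The list also took in RPP1, an RNase P subunit gene whose symbol has the same form. Ribosome biogenesis genes rose in 11 of 107 cases and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 1.09e-06, adjusted p = 0.885 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 10 of 67 with none down (8 and 0 adjusted over the list alone; camera adjusted p = 1.14e-05, adjusted p = 0.556 with an estimated correlation). The library of 0.5% glucose 7 mM K replicate 2 is in neither group compared, but enters the shared estimate of spread, the count filter and the scaling. Without it, 119 cytosolic ribosomal protein genes, 77 ribosome biogenesis genes and 36 mitochondrial ribosomal protein genes rose at almost the same medians, 0.61, 0.66 and 0.43. Glucose-repressed carbon metabolism genes gained a call upward without that library (camera adjusted p = 0.0228, adjusted p = 0.92 with an estimated correlation), and sulfate and methionine genes downward without 2% glucose 1 mM K replicate 3 (0.0469).

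Of the transport genes set in advance, TRK1, the high-affinity potassium transporter gene, measured 143 ± 5.90 CPM at 7 mM and 156 ± 18.4 CPM at 1 mM K (edgeR adjusted p = 0.597), and neither TRK2 (edgeR adjusted p = 0.707) nor the outward channel gene TOK1 (edgeR adjusted p = 0.561) passed the test. PMA1, the plasma membrane proton pump gene (chromosome VII, 479910 to 482666), fell by 1.19 ± 0.27 on the log2 scale (edgeR adjusted p = 0.00733), a call lost under library totals and under WBGene scaling. ENA1, a sodium exporter gene with near-identical neighbours ENA2 and ENA5, rose by 0.94 ± 0.28 (edgeR adjusted p = 0.0253). The ENA1 call was lost without 2% glucose 7 mM K replicate 1, 2 or 3 (0.91, 0.97 and 0.97) or 2% glucose 1 mM K replicate 1 or 2 (0.88 and 0.86). In all, 803 genes rose and 916 fell, so that 46.7% of changed genes rose, against 67.8% under upper-quartile scaling, 67.1% under library totals and 68.7% under WBGene scaling. The total of 1719 became 3111 without 0.5% glucose 7 mM K replicate 2, 1087 without 2% glucose 7 mM K replicate 1 and 1075 without 2% glucose 7 mM K replicate 3.

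Glucose restriction at 7 mM K compared 0.5% with 2% glucose, plus any batch that follows glucose. Camera called 9 of 31 lists, and 0 with an estimated correlation (3 unadjusted). TPO2 (chromosome VII, 763762 to 765606) fell from 2809 ± 242 to 19.4 ± 4.37 CPM, with a log2 fold change of -7.17 ± 0.34 (edgeR adjusted p = 2.56e-07). PMA1 fell from 7330 ± 1035 to 119 ± 37.0 CPM, with a log2 fold change of -5.95 ± 0.34 (edgeR adjusted p = 5.24e-07). ADY2, an acetate transporter gene (chromosome III, 132273 to 133124), rose from 16.2 ± 1.35 CPM by 9.50 ± 1.24 (edgeR adjusted p = 0.000153), and by 7.01 without 0.5% glucose 7 mM K replicate 2.

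The same library raised the other large increases of glucose restriction at 7 mM K. The respiratory growth gene RGI2 rose by 9.26 and by 7.30 without it, the peroxisomal import gene PEX9 by 6.07 and 4.35, and the fatty acyl-CoA oxidase gene POX1 by 5.94 and 2.80. These 3 calls were not made by DESeq2. In all DESeq2 results, a gene given no adjusted p was also counted as not called. The alcohol dehydrogenase gene ADH2 rose by 8.10, by 5.15 without replicate 2 and by 8.70 without 0.5% glucose 7 mM K replicate 3. Among the falls, the aldehyde dehydrogenase gene ALD5 measured -5.49 and -5.11 without it, and the regulator gene COM2 -5.19 and -4.85. The sulfhydrylase gene MET17 measured -4.88 and -6.01, the hexose transporter gene HXT4 -3.67 and -4.26, and the autophagy gene ATG41 -1.75 and -2.37. TRK2 rose by 1.38 ± 0.40 (edgeR adjusted p = 0.019), and by 0.75 without that library, while the call was lost without 2% glucose 7 mM K replicate 1, 2 or 3 (1.44, 1.33 and 1.41) and with only the 2 groups compared. ENA1 rose by 1.78 ± 0.28, TOK1 rose by 0.51 ± 0.11, and TRK1 did not pass the test (edgeR adjusted p = 0.324).

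Amino acid biosynthesis genes fell in 39 of 56 cases under glucose restriction at 7 mM K and rose in 4 (40 and 4 adjusted over the list alone; camera adjusted p = 2.92e-12, adjusted p = 0.537 with an estimated correlation). ARO3, for aromatic amino acids, fell from 947 ± 93.4 to 137 ± 18.3 CPM, and HIS4, for histidine, from 1263 ± 136 to 97.7 ± 27.1 CPM. Sulfate assimilation and methionine genes fell in 22 of 33 and rose in 1 (23 and 1 adjusted over the list alone; camera adjusted p = 1.35e-11, adjusted p = 0.1 with an estimated correlation). MET16 fell, with -3.34 ± 0.20. Heat shock chaperone genes fell in 22 of 31 with none up (24 and 0 adjusted over the list alone; camera adjusted p = 5.25e-09, adjusted p = 0.545 with an estimated correlation). SSA4 fell, with -3.53 ± 0.38, and SSA2, with -2.63 ± 0.19. Fatty acid oxidation and peroxisome genes rose in 18 of 30 and fell in 3 (19 and 3 adjusted over the list alone; camera adjusted p = 6.55e-05, adjusted p = 0.9 with an estimated correlation). Their median was 1.46, and 0.44 without 0.5% glucose 7 mM K replicate 2. Glucose-repressed carbon metabolism genes rose in 13 of 29 and fell in 2 (16 and 4 adjusted over the list alone; camera adjusted p = 0.00367, adjusted p = 0.653 with an estimated correlation). Without that library their median of 1.00 was 0.44.

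Meiosis and sporulation genes rose under glucose restriction at 7 mM K in 15 of 26 cases and fell in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 0.00144, adjusted p = 0.1 with an estimated correlation). The septin gene SPR28 rose from 2.22 ± 0.536 to 28.7 ± 5.71 CPM. Cytosolic ribosomal protein genes had 15 of 135 down and 3 up (2 and 2 adjusted over the list alone; camera adjusted p = 1.73e-05, adjusted p = 0.91 with an estimated correlation), and that call was lost without 0.5% glucose 7 mM K replicate 2 (camera adjusted p = 0.141, with 25 down and 13 up and a median of -0.18). The autophagy call, with 12 of 37 up and 2 down (12 and 3 adjusted over the list alone; camera adjusted p = 0.0223, adjusted p = 0.9 with an estimated correlation), was also lost without it (camera adjusted p = 0.297). The a-specific and haploid mating list, with 7 of 17 down and 0 up (7 and 0 adjusted over the list alone; camera adjusted p = 0.0344, adjusted p = 0.361 with an estimated correlation), was lost without it and without 0.5% glucose 7 mM K replicate 1 (camera adjusted p = 0.0724 and 0.0561). General stress genes gained a call downward without replicate 2 (camera adjusted p = 0.0142), as did S phase genes upward (0.00875) and mitochondrial ribosomal protein genes upward (0.0312). Ribosome biogenesis genes gained a call downward without replicate 1 of that group (camera adjusted p = 0.00531). Their median of -0.13 was 0.25 without replicate 2, with 28 up and 8 down and no call (camera adjusted p = 0.0617). In all, 1035 genes rose and 1042 fell, a rising share of 49.8% against 61.8% under upper-quartile scaling and 66.0% under WBGene scaling.

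The title of the series sets potassium restriction beside caloric restriction. Both single restrictions lowered SSA4, TPO2, PMA1 and TDA6, and both raised PHO89 and RPS22B. PHO89 rose 28.3-fold under glucose restriction, and 16.0-fold without 0.5% glucose 7 mM K replicate 1. Of 31 heat shock chaperone genes, 18 fell under potassium restriction and 22 under glucose restriction (adjusted p = 0.567 and 0.545 with an estimated correlation). Of 56 amino acid biosynthesis genes, 22 and 39 fell, and 3 and 4 rose (adjusted p = 0.885 and 0.537 with an estimated correlation). Of 37 autophagy genes, 16 fell and none rose under potassium restriction, and 12 rose and 2 fell under glucose restriction (adjusted p = 0.567 and 0.9 with an estimated correlation). The latter camera call was lost without 0.5% glucose 7 mM K replicate 2 (camera adjusted p = 0.297). In the mitosis list, 23 of 32 genes rose under potassium restriction, and 3 rose and 6 fell under glucose restriction, or 6 and 11 without 0.5% glucose 7 mM K replicate 2.

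Across 6127 genes, which are not independent replicates, the log2 fold changes of the single restrictions correlated at r = 0.325 and rho = 0.257, and 57.5% had the same sign. Both comparisons use the 2% glucose 7 mM K libraries, and 100 simulated draws with no effect gave a mean r of 0.505, a mean rho of 0.473 and a same-sign share of 66.8%. With nothing but noise, the shared controls alone give such values, so they set no bound for data in which genes change. The covariance was 0.266, against 0.0542 in those draws, which gave every group the same spread. On log2 CPM it was 0.2407, of which the spread of the control libraries would give 0.0147. Of the called genes, 264 rose in both comparisons, 436 fell in both and 142 moved in opposite directions. Independent lists of those sizes would share 136, 156 and 291 genes. Since 3 control libraries cannot be split into groups of 2, part of the excess may come from the shared controls. Without 0.5% glucose 7 mM K replicate 2, r was 0.436, and 627 genes rose in both, 701 fell in both and 300 moved in opposite directions (361, 321 and 681 for independent lists).

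The main effects of potassium and glucose, each a mean over both levels of the other factor, share noise where the spread differs between groups, as it did at 0.5% glucose 7 mM K. They correlated at r = 0.0475 and rho = 0.0616, and at r = -0.0318 over the 2954 genes called in either single restriction. Of 100 draws simulated with the same spread in every group, 95% had r of -0.0505 to 0.0844 and covariances of -0.0027 to 0.0048, against 0.0285. Those draws do not match the unequal spread of the libraries. On log2 CPM the covariance was 0.0258, and the spread of replicates alone would give -0.0269. The difference of 0.0527 was 0.0910 without 0.5% glucose 7 mM K replicate 2 and 0.0238 without replicate 1. The correlation was 0.192 without 0.5% glucose 7 mM K replicate 2, and 0.0862 without 2% glucose 7 mM K replicate 2. Without 0.5% glucose 7 mM K replicate 1 it was -0.0402, and without 0.5% glucose 7 mM K replicate 3 it was 0.0008.

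**Figure D2:**
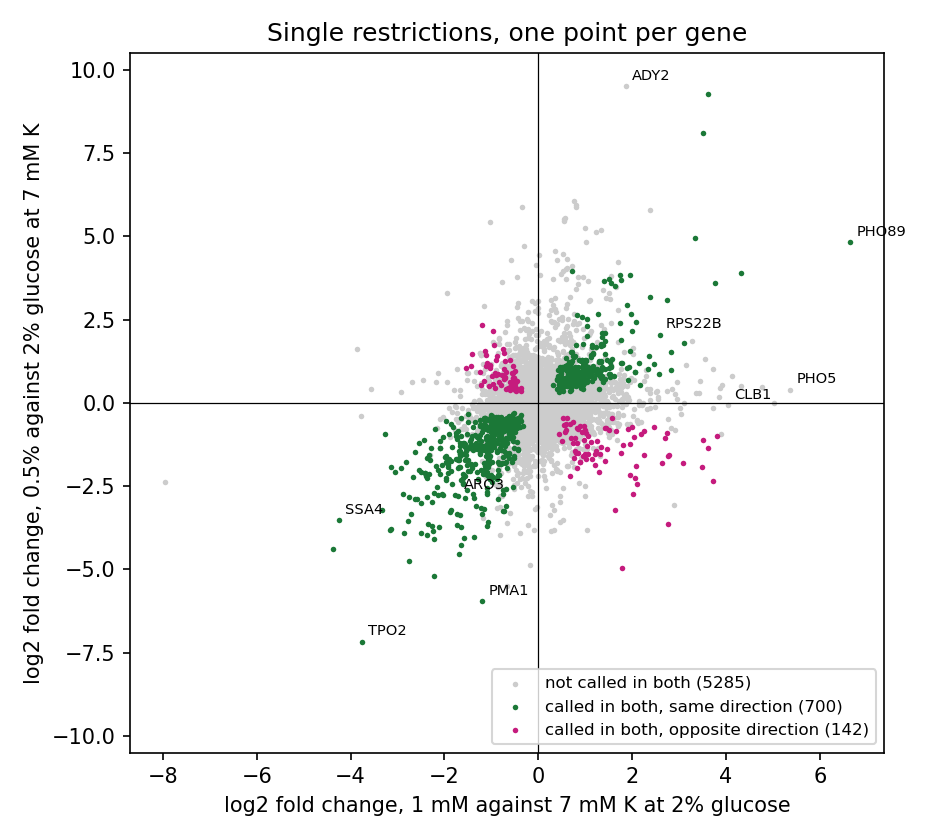
Log2 fold changes of 6127 genes under potassium restriction at 2% glucose (horizontal axis) and glucose restriction at 7 mM K (vertical axis), with 1 point per gene. Of the called genes, 264 rose in both and 436 fell in both, in green, and 142 moved in opposite directions, in magenta; both axes use the 2% glucose 7 mM K libraries, so chance values are shared.

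The single restrictions were also compared with each other, as 1 mM K at 2% glucose against 7 mM K at 0.5% glucose. Camera called 13 of 31 lists, and 1, mitosis, with an estimated correlation, a call lost without any 1 of 9 of the 12 libraries. CIS3, a cell wall protein gene (chromosome X, 122265 to 122948), measured 338 ± 45.8 CPM under potassium restriction and 25.5 ± 1.76 CPM with neither restriction. Its log2 difference between the single restrictions was 6.07 ± 0.19 (edgeR adjusted p = 4.32e-09). The inositol synthesis gene INO1 was higher by 5.41 ± 0.56, and by 6.50 without 0.5% glucose 7 mM K replicate 2. PMA1 was higher by 4.76 ± 0.32, PHO5 by 4.97 ± 0.26, and the methyl cycle gene SAH1 by 4.90 ± 0.42. ADY2 was lower, at -7.63 ± 1.15 and -5.13 without that library, as were the formate dehydrogenase gene FDH2, at -6.46 and -4.54, and FDH1, at -5.24 and -2.57. TRK2 was lower, at -1.59 ± 0.40 and -0.94 without that library, as was TOK1, at -0.60 ± 0.11, a call lost under WBGene scaling. ENA1 was lower, at -0.83 ± 0.28 (edgeR adjusted p = 0.0297), a call lost without 2% glucose 1 mM K replicate 3 (-0.69) or 0.5% glucose 7 mM K replicate 1 or 3 (each -0.69). It was also lost under library totals, WBGene scaling, a replicate block and with only the 2 groups compared. TRK1 did not pass (0.33 ± 0.16), though it passed without 0.5% glucose 7 mM K replicate 3 (0.44).

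Cytosolic ribosomal protein genes were higher under potassium than under glucose restriction in 91 of 135 cases with none lower (camera adjusted p = 3.97e-14, adjusted p = 0.764 with an estimated correlation). Their median was 1.14, and 0.77 without 0.5% glucose 7 mM K replicate 2. Mitosis genes were higher in 23 of 32 with none lower (23 and 0 adjusted over the list alone; camera adjusted p = 3.37e-09, and adjusted p = 0.0301 with an estimated correlation). The latter was 0.2 without 0.5% glucose 7 mM K replicate 2, and 0.163 to 0.278 without 8 other libraries taken singly. Autophagy genes were lower in 24 of 37 with none higher (29 and 1 adjusted over the list alone; camera adjusted p = 1.08e-08, adjusted p = 0.406 with an estimated correlation). Sulfate and methionine genes were higher in 21 of 33 and lower in 2 (22 and 2 adjusted over the list alone; camera adjusted p = 1.24e-07, adjusted p = 0.132 with an estimated correlation). The S-adenosylmethionine synthetase gene SAM2 was higher by 4.75 ± 0.21. Fatty acid oxidation genes were lower in 26 of 30 and higher in 2 (27 and 2 adjusted over the list alone; camera adjusted p = 2.74e-06, adjusted p = 0.753 with an estimated correlation). Without that library their median of -1.74 was -0.73.

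Ribosome biogenesis genes were higher under potassium than under glucose restriction in 40 of 107 cases and lower in 1 (37 and 1 adjusted over the list alone; camera adjusted p = 6.59e-07, adjusted p = 0.766 with an estimated correlation). Amino acid biosynthesis genes were higher in 32 of 56 and lower in 6, also when adjusted over the list alone (camera adjusted p = 3.73e-05, adjusted p = 0.758 with an estimated correlation). Meiosis genes were lower in 15 of 26 (16 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000673, adjusted p = 0.0876 with an estimated correlation). Ergosterol genes were higher in 14 of 24 and lower in 3 (15 and 3 adjusted over the list alone; camera adjusted p = 0.00262, adjusted p = 0.339 with an estimated correlation). S phase genes were higher in 16 of 45 and lower in 4 (17 and 4 adjusted over the list alone; camera adjusted p = 0.0039, adjusted p = 0.764 with an estimated correlation).

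Phosphate genes were higher under potassium than under glucose restriction in 11 of 19 cases and lower in 2, also when adjusted over the list alone (camera adjusted p = 0.00782, adjusted p = 0.339 with an estimated correlation). Nutrient signalling genes were lower in 17 of 38 and higher in 4, also when adjusted over the list alone (camera adjusted p = 0.0201, adjusted p = 0.753 with an estimated correlation). Electron transport genes were higher in 15 of 46 and lower in 4, also when adjusted over the list alone (camera adjusted p = 0.0272, adjusted p = 0.764 with an estimated correlation). The electron transport call was lost without 2% glucose 1 mM K replicate 1 (camera adjusted p = 0.106). General stress genes gained a call as lower without 2% glucose 1 mM K replicate 1 or 2 (0.0453 and 0.0426) or 0.5% glucose 7 mM K replicate 1 or 3 (0.0278 and 0.026). Heat shock chaperone genes gained a call as higher without 2% glucose 1 mM K replicate 3 or 0.5% glucose 7 mM K replicate 3 (0.0423 and 0.0426). So did mitochondrial ribosomal protein genes (0.0202 and 0.0142), which were also called without a count filter (0.0453). In all, 1279 genes were higher and 1413 lower, a higher share of 47.5% against 58.6% under library totals.

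Potassium restriction at 0.5% glucose, 1 mM against 7 mM K, showed what lower potassium changed once glucose was low. Camera called 14 of 31 lists, and 0 with an estimated correlation (1 unadjusted). SCW4, a cell wall glucanase-like gene (chromosome VII, 1048798 to 1049958), rose from 9.82 ± 5.74 to 1208 ± 607 CPM, by 6.96 ± 0.50 (edgeR adjusted p = 2.02e-06), and its paralog SCW10 by 5.45 ± 0.20. The cell wall genes CWP1, CIS3, TOS6 and SRL1 rose by 6.52, 6.33, 6.04 and 6.01, TOS6 by 6.62 without 0.5% glucose 7 mM K replicate 2. PMA1 rose from 119 ± 37.0 to 1592 ± 269 CPM, by 3.75 ± 0.30 (edgeR adjusted p = 4.59e-06). MLS1, the glyoxylate cycle malate synthase gene (chromosome XIV, 406358 to 408022), fell from 1637 ± 300 to 139 ± 4.30 CPM, with a log2 fold change of -3.56 ± 0.24 (edgeR adjusted p = 1.22e-06).

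Other falls at 0.5% glucose were in the pyruvate decarboxylase isoform gene PDC6 (-4.63), the putative transporter gene PUL3 (-4.10, and -3.48 without 0.5% glucose 7 mM K replicate 2), the carnitine acetyltransferase gene YAT2 (-4.09), the zinc-regulated gene ZPS1 (-3.95) and the mitochondrial citrate synthase gene CIT3 (-3.88, -2.17 without that library, and -4.49 without 0.5% glucose 1 mM K replicate 3). DESeq2 did not call CIT3. TRK1 fell by 0.49 ± 0.16 on the log2 scale (edgeR adjusted p = 0.0249), a call lost without 0.5% glucose 7 mM K replicate 3 (-0.41), under library totals and with only the 2 groups compared. ENA1 fell by 0.86 ± 0.28 on the log2 scale (edgeR adjusted p = 0.0229). That call was lost without 0.5% glucose 7 mM K replicate 3 (-0.74) or 0.5% glucose 1 mM K replicate 2 (-0.80) and with only the 2 groups compared. TRK2 (edgeR adjusted p = 0.515) and TOK1 (edgeR adjusted p = 0.377) did not pass the test.

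Cytosolic ribosomal protein genes rose at 0.5% glucose in 114 of 135 cases with none down (124 and 0 adjusted over the list alone; camera adjusted p = 2.68e-16, adjusted p = 0.526 with an estimated correlation). Their median was 1.35, and 0.97 without 0.5% glucose 7 mM K replicate 2. RPL9A, which has a near-identical copy, rose from 39.5 ± 14.9 to 538 ± 66.7 CPM. Ribosome biogenesis genes rose in 57 of 107 and fell in 1 (66 and 1 adjusted over the list alone; camera adjusted p = 1.79e-09, adjusted p = 0.526 with an estimated correlation). Without that library their median of 1.06 was 0.70. Heat shock chaperone genes rose in 15 of 31 with none down (15 and 0 adjusted over the list alone; camera adjusted p = 0.000112, adjusted p = 0.526 with an estimated correlation). SSA2 rose by 2.74 ± 0.19. S phase genes rose in 20 of 45 and fell in 5 (21 and 5 adjusted over the list alone; camera adjusted p = 0.000623, adjusted p = 0.526 with an estimated correlation). RNR1 rose by 5.32 ± 0.37. Sulfate and methionine genes rose in 15 of 33 and fell in 4 (16 and 5 adjusted over the list alone; camera adjusted p = 0.00899, adjusted p = 0.526 with an estimated correlation). The list of ribosomal and small stable RNA genes, which marks RNA quality, rose in 8 of 9 genes (9 and 0 adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.526 with an estimated correlation).

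Tricarboxylic acid and glyoxylate cycle genes fell at 0.5% glucose in 19 of 28 cases with none up (19 and 0 adjusted over the list alone; camera adjusted p = 7.22e-05, adjusted p = 0.187 with an estimated correlation). Glucose-repressed carbon metabolism genes fell in 16 of 29 and rose in 6 (17 and 6 adjusted over the list alone; camera adjusted p = 0.00255, adjusted p = 0.526 with an estimated correlation). Their median was -1.89, and -0.86 without 0.5% glucose 7 mM K replicate 2. Glycolysis and fermentation genes fell in 13 of 23 and rose in 3 (14 and 4 adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.526 with an estimated correlation). Electron transport genes fell in 19 of 46 and rose in 3, also when adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.526 with an estimated correlation). Autophagy genes fell in 16 of 37 and rose in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.526 with an estimated correlation). ATG7 fell, with -1.50 ± 0.16.

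Ammonium and nitrogen catabolite genes fell at 0.5% glucose in 12 of 34 cases and rose in 3 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0396, adjusted p = 0.526 with an estimated correlation). That call was lost without 0.5% glucose 1 mM K replicate 1 or 2 (camera adjusted p = 0.104 and 0.0836). All 5 mitochondrially encoded transcripts tested rose, also when adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.526 with an estimated correlation). The camera adjusted p was 0.055 without 0.5% glucose 7 mM K replicate 2. Such transcripts held 0.0024% ± 0.0013 of yeast counts at 7 mM K and 0.0142% ± 0.0080 at 1 mM K (SD, n = 3). Mitosis genes rose in 15 of 32 and fell in 7 (16 and 7 adjusted over the list alone; camera adjusted p = 0.0437, adjusted p = 0.526 with an estimated correlation). The mitosis call was lost without 0.5% glucose 7 mM K replicate 2 (camera adjusted p = 0.0647), 2% glucose 1 mM K replicate 1 or 3 (0.0533 and 0.056), or 0.5% glucose 1 mM K replicate 2 (0.0513). Retrograde response genes gained a call downward without 0.5% glucose 7 mM K replicate 2 (camera adjusted p = 0.00874). Amino acid genes gained a call upward without 0.5% glucose 7 mM K replicate 1 or 3 (0.0155 and 0.0329) or 0.5% glucose 1 mM K replicate 3 (0.0393). Fatty acid oxidation genes gained a call downward without 0.5% glucose 7 mM K replicate 1 or 3 (0.0155 and 0.0212), and mitochondrial ribosomal protein and mating genes upward without the latter (0.028 and 0.0442). The fatty acid median of -0.84 was 0.14 without 0.5% glucose 7 mM K replicate 2, with 13 up and 8 down and no call (camera adjusted p = 0.409). In all, 1441 genes rose and 1525 fell, a rising share of 48.6% against 22.7% under WBGene scaling.

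Glucose restriction at 1 mM K compared 0.5% with 2% glucose once potassium was low. Camera called 14 of 31 lists, and 0 with an estimated correlation (2 unadjusted). The formate dehydrogenase gene FDH2 rose from 5.17 ± 2.82 to 1276 ± 729 CPM, by 7.94 ± 1.06 (edgeR adjusted p = 0.000266), and by 7.34 without 0.5% glucose 1 mM K replicate 3. The adjoining YPL276W rose by 7.65 ± 1.11 and FDH1 by 6.62 ± 1.21, and by 5.65 without that library; these 3 near-identical genes share reads. The methylated-RNA binding gene PHO92 rose 32.1-fold, and the mitochondrial intron gene BI4 by 5.94 ± 0.70, and by 6.70 without 2% glucose 1 mM K replicate 1. GIT1 fell from 269 ± 80.7 to 13.3 ± 3.79 CPM, with a log2 fold change of -4.33 ± 0.30 (edgeR adjusted p = 7.17e-06), and CLB1 (chromosome VII, 703636 to 705051) from 95.5 ± 30.4 to 8.99 ± 1.08 CPM, with -3.41 ± 0.25 (edgeR adjusted p = 8.83e-06).

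Tricarboxylic acid and glyoxylate cycle genes fell at 1 mM K in 20 of 28 cases and rose in 1 (21 and 1 adjusted over the list alone; camera adjusted p = 6.83e-07, adjusted p = 0.0532 with an estimated correlation). MLS1 fell, with -3.21 ± 0.23. Electron transport and ATP synthase genes fell in 31 of 46 and rose in 4 (31 and 4 adjusted over the list alone; camera adjusted p = 7.87e-06, adjusted p = 0.502 with an estimated correlation). Glycolysis and fermentation genes fell in 10 of 23 with none up (10 and 0 adjusted over the list alone; camera adjusted p = 0.000441, adjusted p = 0.507 with an estimated correlation). The enolase gene ENO1 fell from 8302 ± 1197 to 1074 ± 128 CPM. Sulfate and methionine genes fell in 17 of 33 and rose in 3 (19 and 3 adjusted over the list alone; camera adjusted p = 0.000441, adjusted p = 0.502 with an estimated correlation). Amino acid genes fell in 23 of 56 and rose in 4 (26 and 5 adjusted over the list alone; camera adjusted p = 0.00239, adjusted p = 0.677 with an estimated correlation). Mitosis genes fell in 16 of 32 and rose in 7 (17 and 7 adjusted over the list alone; camera adjusted p = 0.00327, adjusted p = 0.457 with an estimated correlation). Retrograde response genes fell in 6 of 12 and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.0239, adjusted p = 0.502 with an estimated correlation).

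Heat shock chaperone genes rose at 1 mM K in 12 of 31 cases with none down (14 up and 1 down adjusted over the list alone; camera adjusted p = 0.000991, adjusted p = 0.609 with an estimated correlation). Without 0.5% glucose 7 mM K replicate 2, 19 rose, and SSA3 rose by 2.56 ± 0.31 with all libraries. Fatty acid oxidation genes rose in 10 of 30 and fell in 4 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00937, adjusted p = 0.677 with an estimated correlation), and 18 rose without that library. Of 5 mitochondrially encoded transcripts, 4 rose, also when adjusted over the list alone (camera adjusted p = 0.00937, adjusted p = 0.502 with an estimated correlation). The list of ribosomal and small stable RNA genes, set in advance as a sign of RNA quality, rose in 7 of 9 genes, also when adjusted over the list alone (camera adjusted p = 0.00203, adjusted p = 0.507 with an estimated correlation). Its member SNR19 rose by 2.15 ± 0.35.

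Ribosome biogenesis genes rose at 1 mM K in 5 of 107 cases (2 adjusted over the list alone; camera adjusted p = 0.0277, adjusted p = 0.832 with an estimated correlation), and 29 rose without 0.5% glucose 7 mM K replicate 2. Without that library, cytosolic ribosomal protein genes gained a call upward (camera adjusted p = 0.00238), and ergosterol and phosphate genes downward (0.0144 and 0.0453). Ergosterol genes were also called with a replicate block (0.04), without a count filter (0.0371), and without 2% glucose 1 mM K replicate 1 (0.0411), 0.5% glucose 7 mM K replicate 1 (0.0305) or 0.5% glucose 1 mM K replicate 1 or 2 (0.0361 and 0.0344). Autophagy genes gained a call upward without 2% glucose 1 mM K replicate 1 (0.0286) or 0.5% glucose 1 mM K replicate 2 (0.0344). S phase genes did so without 2% glucose 1 mM K replicate 3 (0.0194) or 0.5% glucose 1 mM K replicate 3 (0.00665), and cytosolic ribosomal protein genes also without the latter (0.0263). The ribosome biogenesis median of 0.24 flipped to -0.19 under WBGene scaling and to -0.0022 under library totals. The call was lost without 2% glucose 1 mM K replicate 1 or 2 (camera adjusted p = 0.134 and 0.0796) or 0.5% glucose 1 mM K replicate 1 or 2 (0.147 and 0.0934).

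General stress genes rose at 1 mM K in 12 of 48 cases and fell in 6, also when adjusted over the list alone (camera adjusted p = 0.0277, adjusted p = 0.75 with an estimated correlation). Their median of 0.32 flipped to -0.14 under WBGene scaling, and 19 rose without 0.5% glucose 7 mM K replicate 2. The call was lost without 2% glucose 1 mM K replicate 3 (camera adjusted p = 0.126) or 0.5% glucose 1 mM K replicate 3 (0.466). Glucose-repressed carbon metabolism genes fell in 12 of 29 and rose in 4, also when adjusted over the list alone (camera adjusted p = 0.0277, adjusted p = 0.605 with an estimated correlation). That call was lost without 2% glucose 1 mM K replicate 2 (camera adjusted p = 0.0578) or 0.5% glucose 1 mM K replicate 1 or 2 (0.0857 and 0.0515). TRK1 fell by 0.82 ± 0.16 on the log2 scale (edgeR adjusted p = 0.00234), PMA1 fell by 1.01 ± 0.27 (edgeR adjusted p = 0.014), and ENA1 did not pass the test (edgeR adjusted p = 0.954). TOK1 rose by 0.48 ± 0.11, a call lost under library totals and WBGene scaling. TRK2 rose 2.42-fold (edgeR adjusted p = 0.0268). The TRK2 call was lost without 2% glucose 1 mM K replicate 1, 2 or 3 (2.30-fold, 2.17-fold and 2.62-fold), without 0.5% glucose 1 mM K replicate 3 (1.71-fold) and under WBGene scaling. In all, 1001 genes rose and 1129 fell, a rising share of 47.0%. It was 36.4% under upper-quartile scaling, 30.7% under library totals and 20.4% under WBGene scaling.

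Both restrictions together were compared with neither, as 0.5% glucose 1 mM K against 2% glucose 7 mM K. Camera called 13 of 31 lists, and 0 with an estimated correlation (1 unadjusted). HO rose from 5.14 ± 0.996 to 346 ± 64.6 CPM, by 6.07 ± 0.35 (edgeR adjusted p = 3.14e-07), SCW4 by 6.01 ± 0.47 and RGI2 by 7.90 ± 0.97, a call that DESeq2 did not make. YRO2, a membrane protein gene, fell from 9819 ± 84.1 to 254 ± 21.5 CPM, with a log2 fold change of -5.27 ± 0.82 (edgeR adjusted p = 0.000313). TDA6, TPO2 and the gene of unknown function YNR066C also fell, with -4.65, -4.42 and -4.18. TRK1 fell by 0.70 ± 0.16 on the log2 scale (edgeR adjusted p = 0.00382), and PMA1 fell by 2.20 ± 0.28 (edgeR adjusted p = 8.34e-05). ENA1 rose by 0.92 ± 0.28 (edgeR adjusted p = 0.0177), a call lost without 2% glucose 7 mM K replicate 1 or 3 (0.85 and 0.94) and under WBGene scaling. TOK1 rose by 0.39 ± 0.11, a call lost without 2% glucose 7 mM K replicate 1 (0.35), under library totals and under WBGene scaling. TRK2 rose by 1.06 ± 0.40 (edgeR adjusted p = 0.0443), a call lost with a replicate block, without a count filter and with protein-coding rows alone. It was also lost without 2% glucose 7 mM K replicate 1, 2 or 3 (1.07, 0.96 and 1.09), 2% glucose 1 mM K replicate 1, 2 or 3 (each 1.03), or 0.5% glucose 1 mM K replicate 2 or 3 (1.22 and 0.58).

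Ribosome biogenesis genes rose under both restrictions in 48 of 107 cases with none down (47 and 0 adjusted over the list alone; camera adjusted p = 2.58e-07, adjusted p = 0.684 with an estimated correlation), and 89 rose without 0.5% glucose 7 mM K replicate 2. Cytosolic ribosomal protein genes rose in 46 of 135 with none down (28 and 0 adjusted over the list alone; camera adjusted p = 1.09e-06, adjusted p = 0.748 with an estimated correlation), and 124 rose without that library. S phase genes rose in 27 of 45 and fell in 4 (27 and 4 adjusted over the list alone; camera adjusted p = 2.92e-06, adjusted p = 0.607 with an estimated correlation). The cohesin gene MCD1 rose by 4.63 ± 0.31. Amino acid genes fell in 35 of 56 and rose in 4 (36 and 4 adjusted over the list alone; camera adjusted p = 2.19e-06, adjusted p = 0.607 with an estimated correlation). Tricarboxylic acid cycle genes fell in 20 of 28 and rose in 1 (20 and 1 adjusted over the list alone; camera adjusted p = 1.14e-05, adjusted p = 0.131 with an estimated correlation), and electron transport genes fell in 23 of 46 and rose in 1 (23 and 1 adjusted over the list alone; camera adjusted p = 0.000624, adjusted p = 0.607 with an estimated correlation).

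Sulfate and methionine genes fell under both restrictions in 20 of 33 cases and rose in 5, also when adjusted over the list alone (camera adjusted p = 0.00172, adjusted p = 0.607 with an estimated correlation). Glycolysis genes fell in 12 of 23 and rose in 1 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0147, adjusted p = 0.637 with an estimated correlation). Phosphate genes rose in 10 of 19 and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.0197, adjusted p = 0.607 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 20 of 67 and fell in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 0.00226, adjusted p = 0.607 with an estimated correlation), and 32 rose without 0.5% glucose 7 mM K replicate 2. The list of ribosomal and small stable RNA genes, set in advance as a sign of RNA quality, rose in 8 of 9 genes (9 adjusted over the list alone). Its camera adjusted p was 0.00172, and 0.607 with an estimated correlation.

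All 5 mitochondrially encoded transcripts rose under both restrictions, also when adjusted over the list alone (camera adjusted p = 0.00972, adjusted p = 0.607 with an estimated correlation). The call was lost without 0.5% glucose 7 mM K replicate 2 (camera adjusted p = 0.0511). Retrograde response genes fell in 6 of 12 and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.0423, adjusted p = 0.607 with an estimated correlation). That call was lost without 2% glucose 7 mM K replicate 1 (camera adjusted p = 0.0554) or 0.5% glucose 1 mM K replicate 1 or 2 (0.0612 and 0.0639). Heat shock chaperone and general stress genes gained calls downward without 0.5% glucose 1 mM K replicate 3 (camera adjusted p = 0.019 and 0.0257). In all, 1400 genes rose and 1504 fell, a rising share of 48.2% against 34.4% under WBGene scaling.

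**Figure D3:**
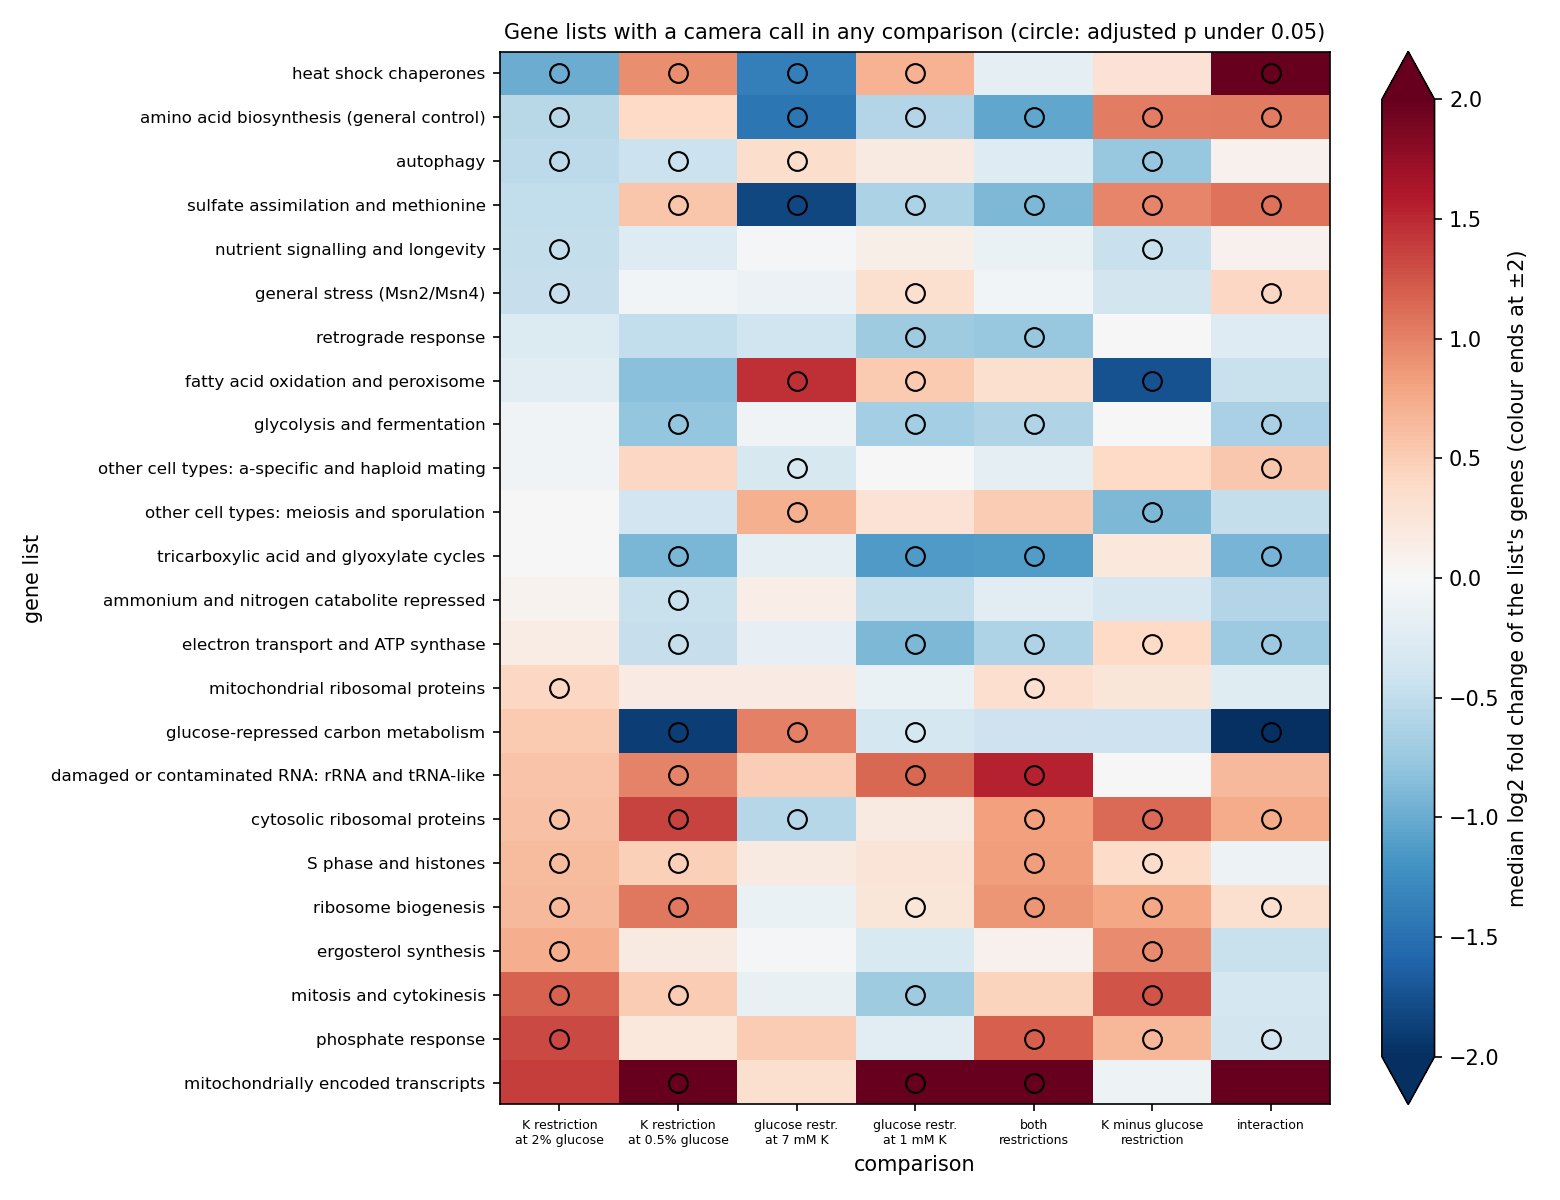
Median log2 fold change of the genes in each list (vertical axis) in each comparison (horizontal axis), in colour, with a circle where camera gave an adjusted p under 0.05 at its preset correlation. Of 31 heat shock chaperone genes, 18 fell under potassium restriction at 2% glucose and 15 rose at 0.5% glucose (adjusted p = 0.567 and 0.526 with an estimated correlation); the direction of the interaction flipped under another scaling for ribosome biogenesis, general stress and mating genes.

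The interaction asked whether the effect of potassium differed between the glucose levels. Camera called 12 of 31 lists, and 0 with an estimated correlation (3 unadjusted). TPO2 had an interaction of 6.51 ± 0.40 (edgeR adjusted p = 6.52e-06), with an effect of -3.76 at 2% glucose and 2.75 at 0.5% glucose. PMA1 had an interaction of 4.94 ± 0.40 (edgeR adjusted p = 1.57e-05), with -1.19 and 3.75. PHO89 had -5.89 ± 0.94 (edgeR adjusted p = 0.000853), and -5.10 without 0.5% glucose 7 mM K replicate 1. MLS1 had -4.26 ± 0.31 (edgeR adjusted p = 1.09e-05), with 0.70 at 2% glucose, a call lost without 2% glucose 7 mM K replicate 1, 2 or 3 (0.70, 0.71 and 0.73) or 2% glucose 1 mM K replicate 3 (0.54), and -3.56 at 0.5% glucose.

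Heat shock chaperone genes had a positive interaction in 24 of 31 cases and a negative one in none (25 and 0 adjusted over the list alone; camera adjusted p = 1.09e-11, adjusted p = 0.282 with an estimated correlation). SSA2 had 3.48 ± 0.26 and SSA4 4.64 ± 0.51, the latter 4.04 without 0.5% glucose 1 mM K replicate 3. Amino acid genes had 27 of 56 positive and 3 negative (31 and 4 adjusted over the list alone; camera adjusted p = 2.3e-05, adjusted p = 0.665 with an estimated correlation), and sulfate and methionine genes 18 of 33 positive and 1 negative (19 and 2 adjusted over the list alone; camera adjusted p = 5.26e-05, adjusted p = 0.282 with an estimated correlation). Glucose-repressed carbon metabolism genes had 16 of 29 negative and 2 positive (17 and 2 adjusted over the list alone; camera adjusted p = 5.26e-05, adjusted p = 0.282 with an estimated correlation), and tricarboxylic acid cycle genes 14 of 28 negative and 1 positive (15 and 1 adjusted over the list alone; camera adjusted p = 0.000754, adjusted p = 0.282 with an estimated correlation). Electron transport genes had 15 of 46 negative and 4 positive (21 and 5 adjusted over the list alone; camera adjusted p = 0.00369, adjusted p = 0.665 with an estimated correlation), and 26 were negative without 0.5% glucose 7 mM K replicate 2. Phosphate genes had 6 of 19 negative with none positive (6 and 0 adjusted over the list alone; camera adjusted p = 0.0107, adjusted p = 0.282 with an estimated correlation).

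Cytosolic ribosomal protein genes had a positive interaction in 6 of 135 cases and a negative one in 1 (2 and 1 adjusted over the list alone; camera adjusted p = 5.26e-05, adjusted p = 0.747 with an estimated correlation). Their median was 0.74, and without 0.5% glucose 7 mM K replicate 2 it was 0.34, with 32 positive. Glycolysis genes had 6 of 23 negative and 1 positive, also when adjusted over the list alone (camera adjusted p = 0.0198, adjusted p = 0.747 with an estimated correlation). The glycolysis call was lost without 0.5% glucose 7 mM K replicate 1 (camera adjusted p = 0.054), and 12 were negative without replicate 2. Ribosome biogenesis genes had 7 of 107 positive (3 adjusted over the list alone; camera adjusted p = 0.0198, adjusted p = 0.874 with an estimated correlation), with a median of 0.31 that flipped to -0.05 under library totals and -0.39 under WBGene scaling. The ribosome biogenesis call was lost without 0.5% glucose 7 mM K replicate 2 (camera adjusted p = 0.85, with 11 positive and 10 negative), 2% glucose 1 mM K replicate 1 (0.0655) or 0.5% glucose 1 mM K replicate 1 or 2 (0.0795 and 0.0555).

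General stress genes had a positive interaction in 13 of 48 cases and a negative one in 2, also when adjusted over the list alone (camera adjusted p = 0.0121, adjusted p = 0.747 with an estimated correlation). Their median of 0.42 flipped to -0.20 under WBGene scaling, and 23 were positive without 0.5% glucose 7 mM K replicate 2. The call was lost without 2% glucose 1 mM K replicate 3 (camera adjusted p = 0.0527), 0.5% glucose 7 mM K replicate 1 (0.0712) or 0.5% glucose 1 mM K replicate 3 (0.107). Mating genes had 5 of 17 positive, also when adjusted over the list alone (camera adjusted p = 0.0366, adjusted p = 0.282 with an estimated correlation), with a median of 0.53 that flipped to -0.10 under WBGene scaling. The mating call was lost without 0.5% glucose 7 mM K replicate 1 or 2 (camera adjusted p = 0.0515 and 0.166) or 0.5% glucose 1 mM K replicate 1 (0.0626). Negative calls were gained by mitosis genes without 2% glucose 1 mM K replicate 1 (0.0475) and by ammonium and nitrogen catabolite genes without 0.5% glucose 7 mM K replicate 3 or 0.5% glucose 1 mM K replicate 3 (0.0317 and 0.0173). Ribosomal and small stable RNA genes gained a positive call without 0.5% glucose 1 mM K replicate 1 (0.0279).

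In all, 904 genes had a positive and 931 a negative interaction, a positive share of 49.3% against 33.0% under upper-quartile scaling, 30.5% under library totals and 16.6% under WBGene scaling. The total of 1835 became 2927 without 0.5% glucose 7 mM K replicate 2, and 1832 genes were called in the same direction in both. ENA1 had an interaction of -1.81 ± 0.39 (edgeR adjusted p = 0.00525). TRK1 did not pass the test (-0.61 ± 0.23, edgeR adjusted p = 0.0612), though it passed without 2% glucose 1 mM K replicate 3 (-0.71) or 0.5% glucose 7 mM K replicate 2 (-0.77).

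**Figure D4:**
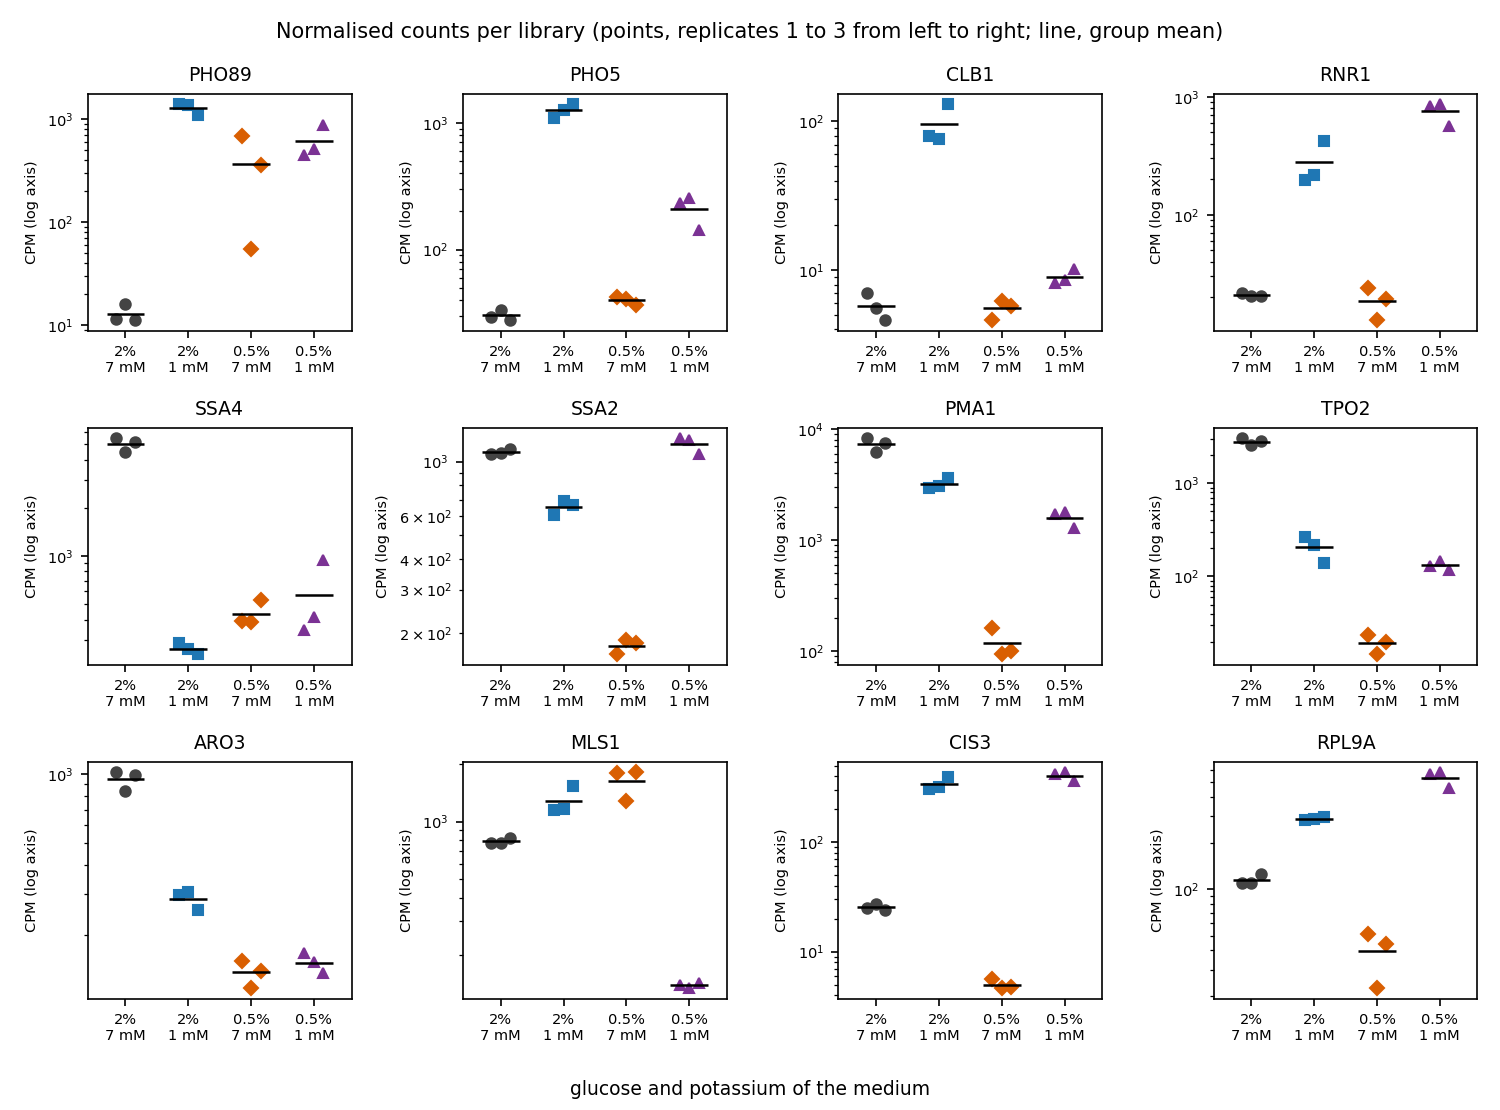
CPM per library on log axes for 12 genes in the 4 media, as points for replicates 1 to 3 and a line for the group mean. PMA1 measured 7330 CPM with neither restriction, 3204 with potassium restriction, 119 with glucose restriction and 1592 with both; RPL9A has a near-identical copy that shares its reads.

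The libraries carried the marks of the stated strain. LEU2, LYS2 and URA3, which BY4742 lacks, had 0 counts in all 12 libraries, as did the a-factor genes MFA1 and MFA2, which a strain of the alpha mating type does not express. HIS3, of which BY4742 keeps a part, had 19 to 1087 counts. The alpha-specific genes MF(ALPHA)1 and STE3 had 27 to 3745 and 119 to 1614 counts. The a-specific genes STE2 and BAR1 had 52 to 127 and 23 to 100 counts. The counts are limited in that the files do not state whether strand was used, so antisense and overlapping genes cannot be told apart. Near-identical copies such as those of ENA and ribosomal protein genes share reads. Related genes such as those of SSA, CLB and PHO5 may share some.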

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

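The interaction test was planned, and the tests of its causes, the splits, and the tests of the WBGene rows and of the library that stood apart were chosen after results were seen. The potassium effect differed between the glucose levels, by the edgeR test of the interaction, for 1835 genes. The named genes with the largest positive values were TPO2 (6.51), SPI1 (5.97), HXT4 (5.13), BI4 (5.05), PMA1 (4.94) and YOR338W (4.85). SPI1 had 6.83 without 0.5% glucose 7 mM K replicate 2 and 5.27 without 0.5% glucose 1 mM K replicate 3, and HXT4 had 5.72 without the former. BI4, which lies within the COB gene, had 5.86 without 0.5% glucose 7 mM K replicate 2, 5.78 without 2% glucose 1 mM K replicate 1 and 4.46 without 0.5% glucose 1 mM K replicate 3.

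The largest negative values were ENA2 (-7.58), ADH2 (-7.02), PDC6 (-6.71), PHO89 (-5.89), PUT4 (-5.81) and ADY2 (-5.09). Without 0.5% glucose 7 mM K replicate 2, ADH2 had -4.06 and ADY2 had -2.61. ENA2, a near-identical copy of ENA1, had 0, 1.96 and 0 CPM in replicates 1 to 3 under both restrictions, so its fitted value rests on 1 library there and no value is given without it. It had -8.24 without 2% glucose 7 mM K replicate 1 and -6.96 without 0.5% glucose 1 mM K replicate 1. PHO89 had -5.10 without 0.5% glucose 7 mM K replicate 1.

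Camera called 12 lists for the interaction at its preset correlation, and 0 with an estimated correlation (3 unadjusted). Their medians were 2.02 for heat shock chaperones, 1.09 for sulfate and methionine, 1.05 for amino acid biosynthesis, 0.74 for cytosolic ribosomal proteins, 0.53 for mating, 0.42 for general stress and 0.31 for ribosome biogenesis. They were -1.998 for glucose-repressed carbon metabolism, -0.93 for the tricarboxylic acid cycle, -0.72 for electron transport, -0.65 for glycolysis and -0.37 for phosphate. With 0.5% glucose 7 mM K replicate 2 left out, cytosolic ribosomal proteins had 0.34, ribosome biogenesis 0.0007 and general stress 0.73. Under WBGene scaling they were -0.39 for ribosome biogenesis, -0.20 for general stress and -0.10 for mating, and under library totals -0.05 for ribosome biogenesis.

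The library that stood apart cannot be the whole cause of the interaction, since 1832 of its genes were called in the same direction without it. Scaling cannot be the whole cause either, since at least 1259 genes kept their call and direction under each of the 4 other scalings, taken 1 at a time. Of 100 assignments of the 12 libraries to the groups, the real one and others drawn at random, 1, the real one, gave as many genes, and the highest other gave 94. Random assignments also mix the other effects into the spread. For each of the 6 pairwise comparisons, 1 of 10 splits gave as many genes as the real one and the highest other gave 0 by edgeR (76 to 1146 unadjusted), but 10 splits cannot give a share under 0.05.

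The WBGene rows, which no supplied table named, held 34.0% to 41.6% of the counts of a library. Of 8796 such rows tested with edgeR, 2536 were called for glucose restriction at 7 mM K, 2265 for glucose restriction at 1 mM K, 2260 for both restrictions, 3243 between the single restrictions, 195 for potassium restriction at 0.5% glucose, 19 for potassium restriction at 2% glucose and 12 for the interaction. With a replicate block the counts were, in the same order, 3655, 3269, 3091, 4186, 387, 88 and 27. Yeast reads counted at those rows cannot be the whole cause, since 2.217% of them were called for potassium restriction at 0.5% glucose, where 2966 of 6127 yeast genes were called. Batches that follow the replicate number may have a part for libraries numbered 1. Their deviations correlated at a mean of 0.4897 across rows, which are not independent, and at -0.3469 with those of other numbers. The means of -0.3469, and of 0.2632 for pairs both numbered 2 or both 3, cannot show such batches. Deviations were from the mean of 3 libraries, so a shift of number 1 alone gives both. In these rows (2536 called) and in yeast genes, batches by glucose level could not be told from an effect of glucose. Every library of a level would share its batch.

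The library of 0.5% glucose 7 mM K replicate 2 stood apart from its partners. A mixture with another library of the series does not account for it, since 741 of its genes lay over 2-fold outside the range of the other 11 libraries. Across all genes its deviation did not follow the change in replicates 1 and 3. Its deviation correlated with that change at r = -0.0041 across genes, which are not independent replicates. Both contain replicates 1 and 3, whose noise alone would give a covariance of -0.0278, and with that removed r was 0.0253. This r cannot exclude a larger change in part of the genes. The deviation also correlated at r = 0.2814 with the glucose effect at 1 mM K and -0.2374 with the potassium effect at 2% glucose. With the deviation of 0.5% glucose 1 mM K replicate 3, r was 0.4255. A culture at another growth stage or handled apart could give the shift of -1.79 in cytosolic ribosomal protein genes, but the labels give no harvest density, and no biological explanation was tested.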

How the results depend on the processing

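Tests with WBGene scaling, quality weights and protein-coding rows, and the lists that gained calls or were tested with an estimated correlation without 1 library, were chosen after results were seen. No called gene named by the rule changed direction except PHO86 under glucose restriction at 1 mM K, with -0.0085 under WBGene scaling. DESeq2 size factors kept the call and direction of all 531 values of named genes and all 87 list calls. For potassium restriction at 2% glucose, 1719 genes became 3390 with only the 2 groups compared, 557 at a fold threshold of 1.5, 1061 under WBGene scaling and 3859 with limma voom and quality weights. Potassium restriction at 0.5% glucose became 1805 with only the 2 groups, and the single restrictions compared 1462 so and 1669 under WBGene scaling. The fold threshold gave 857 genes for glucose restriction at 7 mM K, 1391 for both restrictions, 1409 for potassium restriction at 0.5% glucose, 772 for glucose restriction at 1 mM K, 1093 for the single restrictions compared and 896 for the interaction. Quality weights gave 3684 for glucose restriction at 7 mM K, 4689 for both restrictions, 3791 for glucose restriction at 1 mM K and 3733 for the interaction. Leaving out 1 library gave 1075 to 3111 genes for potassium restriction at 2% glucose and 1362 to 2927 for the interaction. A fold threshold tests a stricter claim, and the cause of the other shifts was not tested.

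With an estimated correlation, camera called 1 list for potassium restriction at 2% glucose (mitosis), 1 for the single restrictions compared (mitosis), and 0 for glucose restriction at 7 mM K, both restrictions, potassium restriction at 0.5% glucose, glucose restriction at 1 mM K and the interaction, against 1 to 4 unadjusted. Both mitosis calls were lost without any 1 of 9 libraries, with 0.255 and 0.2 without 0.5% glucose 7 mM K replicate 2. The tricarboxylic acid cycle list gained such a call for glucose restriction at 1 mM K without any 1 of 10 libraries, for both restrictions without either of 2 and for potassium restriction at 0.5% glucose without 1. The sulfate and methionine list gained one without 2% glucose 1 mM K replicate 3 for glucose restriction at 7 mM K, the single restrictions compared and the interaction. At the preset correlation, leaving out 1 library added calls for 2 to 6 lists per comparison. The correlation of the main effects was 0.0924 with the DESeq2 Wald test and 0.1808 with quality weights, and -0.0402 to 0.1921 without 1 library. The cause was not tested.

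Libraries of different groups share replicate numbers, but the labels do not say that a number marks a shared culture or day. With a replicate block, edgeR called 1403, 1792, 2681, 2742, 1869, 2377 and 1534 genes for potassium restriction at 2% glucose, glucose restriction at 7 mM K, both restrictions, potassium restriction at 0.5% glucose, glucose restriction at 1 mM K, the single restrictions compared and the interaction. Deviations of libraries with the same number correlated at -0.366 to 0.328 across genes, above 0.1 in 3 of 18 pairs, and those with other numbers at -0.402 to 0.426. Depth limits what can be seen in weakly expressed genes, where 3 counts came to 0.4558 CPM in the library of 2% glucose 7 mM K replicate 1.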

Other observations

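The list tests in this part were set before the data were examined, and FIT2 and the tests on WBGene rows were chosen after results were seen. The potassium and cation transport list had no camera call in any comparison. Of its 27 genes, 4 rose and 7 fell under potassium restriction at 2% glucose (5 and 7 adjusted over the list alone; camera adjusted p = 0.564), and 8 rose and 10 fell at 0.5% glucose (8 and 10 adjusted over the list alone; camera adjusted p = 0.758). In the other comparisons its camera adjusted p was 0.402 to 0.852. Of 28 hexose transport and glucose sensing genes, 3 were higher and 11 lower under potassium than under glucose restriction (4 and 12 adjusted over the list alone; camera adjusted p = 0.0576). The list was called without 2% glucose 1 mM K replicate 2 or 0.5% glucose 7 mM K replicate 3 (camera adjusted p = 0.0423 and 0.0166), and with a replicate block (0.0497). HXT6, a high-affinity glucose transporter gene with a near-identical copy HXT7, was higher by 3.81 ± 0.45 there (edgeR adjusted p = 8.05e-05). HXT3, a low-affinity transporter gene, rose from 75.2 ± 18.2 to 375 ± 38.6 CPM under potassium restriction at 0.5% glucose (edgeR adjusted p = 5.83e-06). In the other comparisons the adjusted p of the hexose list was 0.107 to 0.981.

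The calcineurin list, with 17 genes, had camera adjusted p values of 0.331 to 0.917 over the 7 comparisons. The iron list, with 24 genes, had 0.0997 to 0.988, the lowest under both restrictions, where 8 genes fell and none rose by edgeR, also when adjusted over the list alone. It was called there without 2% glucose 7 mM K replicate 3 or 0.5% glucose 1 mM K replicate 3 (camera adjusted p = 0.0395 and 0.0413). FIT2, a cell wall gene for iron uptake, fell there, with -2.16 ± 0.35 (edgeR adjusted p = 0.000394). The trehalose and glycogen list, with 21 genes, had 0.127 to 0.973. Without 0.5% glucose 1 mM K replicate 3 it was called downward under both restrictions and under potassium restriction at 0.5% glucose (camera adjusted p = 0.0193 and 0.0364). The antioxidant list, with 36 genes, had 0.099 to 0.942, the lowest for glucose restriction at 1 mM K, where 12 genes rose and 6 fell (15 and 6 adjusted over the list alone). The proteasome list, with 34 genes, had 0.331 to 0.941.

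In the WBGene rows, the first principal component carried 77.2% of the variance and separated the glucose levels. Correlations of log values across rows had a median of 0.973 within a group, 0.962 between groups of the same glucose level and 0.854 between glucose levels. Deviations of same-number libraries correlated above 0.1 in 16 of 18 pairs there (mean 0.3387). Subtracting group means makes that of other numbers negative (-0.1556). Pairs numbered 1 had 0.388 to 0.738 there, and a mean of -0.0307 in yeast genes.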
